A study of Mus musculus with 8 samples.

How the data were processed

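RNA was measured by sequencing in 8 mouse samples, 6 of intestinal crypts and 2 of intestinal stem cells, each a group of its own. Per the labels, crypts were flash frozen, RNA was taken up in Trizol and libraries were run on a BGI-500 instrument, while total RNA of stem cells was depleted of ribosomal RNA and run on a HiSeq X-Ten. Per the submitters' processing notes, HISAT2, featureCounts and edgeR were used with the builds GRCm38 and mm10. The notes give no versions and do not say which tool made which table.

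Gene values of the crypts are FPKM as deposited, that is fragments scaled by the authors for gene length and library size and rounded to 2 decimals, with the unit per the file headers. The table has 20718 lines, of which 3760 hold no value in any of the 6 libraries, 1 of them without a gene identifier. The other 16958 genes were used, and 92 of these were listed at 0 in all 6 libraries. Symbols and coordinates were looked up by gene identifier in the RefSeq annotation of GRCm38, which named 16916 of them and left 42 unnamed. For the repeats, the authors' deposited table gives a log2 fold change between columns headed MT and WT, with base 2 per the file headers and the ratio of those columns. The p-value and adjusted p-value of each repeat are the authors' own as deposited, and the test behind them is not stated. The 2 columns with values per sample in that table were not used, because their titles do not name a sample or a tissue. Stem cell gene values were not analysed here, so neither the stem cell genes nor their overlap with the crypts are reported.

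The comparisons, the rules, the gene lists and the alternatives were fixed before the data were examined, except where a choice is said to have been made later. A gene was tested when its mean over the 6 crypt libraries was at least 1 FPKM, which held for 10862 genes, 10847 of them with a symbol. A gene under 1 FPKM in WT passed this filter only through higher values in knockouts, which can raise the medians of lists with such members. The log2 ratio of a knockout library to WT was taken after a pseudocount of 1 FPKM was added to both values. A gene counted as higher or lower when it was at least 2-fold from WT, in 1 library or in all 5. VEMD8 was set against VEMD2 by the same rule. Because all 5 ratios share the WT library, the count was repeated with each of the 6 libraries as the reference and in 100 simulations of 5 libraries without any difference, with noise taken from VEMD2 and VEMD3 or from VEMD6 and VEMD8.

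No paired analysis was possible because each group holds 1 library. With 1 library per group there is also no test, no p-value and no error, and differences are described by size alone. The depth is unknown, since FPKM without counts do not give it, and steps left by whole counts could not be read from ratios of low values, where the fullest bin held 5.36% to 6.66% of genes and the next 4.79% to 5.64%. No intervals from counting could be given.

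There were 37 gene lists, of stem cells, reserve stem cells, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, broad epithelium, proliferation, p53 targets, DNA repair, interferon-stimulated genes, antigen presentation, necroptosis, apoptosis and pyroptosis, nucleic acid sensing, cytokines, antimicrobial response, leukocytes, stroma, red blood cells, fetal and regenerative epithelium, germline, protocadherins, Wnt, Notch, unfolded protein response, heat shock, xenobiotics, fatty acids, cholesterol, partners of SETDB1, the Y chromosome, X inactivation, the mitochondrial genome, pancreas, and nerve and muscle of the gut wall. Some genes stand in more than 1 list. For each list the median ratio of the tested members was set among 10000 random lists of the same size, drawn from 20 bins of mean expression, and given a 95% bootstrap interval over members from 1000 draws. Neither is a test between mice. Lists with fewer than 3 tested members got no median.

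Genes named in the text followed a fixed rule. It takes Setdb1, the 10 highest and 10 lowest genes by the smallest of the 5 ratios, or by the ratio of VEMD8 to VEMD2, among genes with a mean of at least 5 FPKM and a symbol that is more than a model number, and up to 4 members per list in the order of the size of their ratio. For repeats it takes the 8 highest and 4 lowest LTR features. Defa21, single IAP, LINE-1 and ribosomal features, the genes 13222 and 13223, and the genes named for gut region, gene clusters and near copies stand outside the rule and were chosen after their values were seen. Not all genes that the rule names are reported here. Repeats were grouped by their names.

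The rules were tested on simulated data, in which 50 genes each were set 1.5, 2, 4 or 8 times from WT among 10821 genes tested. The rule for all 5 libraries found 2%, 6%, 92% and 100% of them, and the rule for 1 library 4%, 34%, 100% and 100%. The altered genes all had a mean of at least 5 FPKM, so these shares do not cover tested genes between 1 and 5 FPKM. Of 10662 genes without a difference, the rule for all 5 called 63 (0.591%) and that for 1 library 254 (2.38%). Simulated lists without a shift had medians from -0.09 to 0.094, and lists shifted by 1 had medians from 0.93 to 1.13. Noise in these simulations came from VEMD2 and VEMD3, the pair closest to each other, and was drawn separately for each gene. They do not cover noisier libraries or lists whose genes vary together.

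Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, libraries rescaled to the median ratio of genes, thresholds of 1.5-fold and 4-fold, and leaving out each knockout library in turn. Leaving out VEMD6 and VEMD8 together, or VEMD2, VEMD3 and VEMD4 together, was added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 with a fixed random seed of 11.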

Results

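RNA was sequenced from intestinal crypts and from intestinal stem cells of C57BL/6 mice aged 8 weeks, with or without deletion of Setdb1, a methyltransferase that places repressive marks on lysine residues of histone H3. The 8 samples form 8 groups of 1 library each. Crypts came from a control mouse with floxed Setdb1 (WT) and from mice whose intestinal epithelium had lost the gene, in libraries titled VEMD2, VEMD3, VEMD4, VEMD6 and VEMD8. Tamoxifen, which switches on the recombinase, was given once at 800 mg/kg per the labels of all crypt samples, WT included. The stem cell pair, WT and MUT, came from mice with the recombinase under the Lgr5 promoter, given 200 mg/kg on 3 days. VEMD is not spelled out in the labels. The title of the deposited gene table speaks of days, so the number in each library's name is used here only as a label. No group has a replicate, so no value below carries an error and no difference was tested. Words such as higher and lower describe these libraries alone. The deposited values are FPKM with no counts, so the depth behind each value is unknown.

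Setdb1 itself (gene 84505, chromosome 3, 95323525 to 95357202 on GRCm38) was at 9.42 FPKM in the WT crypt library. It was lower in every one of the 5 knockout libraries, at 6.64 in VEMD2, 7.03 in VEMD3, 5.49 in VEMD4, 3.53 in VEMD6 and 4.95 in VEMD8. The log2 ratio to WT, taken after adding 1 FPKM to both values as for all ratios below, was lowest in VEMD6, at -1.20, or -0.99 after the libraries were rescaled to their median gene. A value for the whole gene cannot show whether single exons were lost. The sum of FPKM over all genes was 585501 in WT and lay between 481519 and 566585 in the knockouts. The median ratio over the tested genes was 0.09, 0.12, 0.03, -0.23 and -0.06 in VEMD2, VEMD3, VEMD4, VEMD6 and VEMD8, and the ratios of VEMD6 and VEMD3 are to be read against these shifts. Across genes within these libraries, which are not independent replicates, log2 values correlated with WT at 0.965 in VEMD2 and at 0.917 to 0.934 in the others. VEMD6 and VEMD8 were closest to each other, at 0.970, as were VEMD2 and VEMD3, at 0.981.

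The first comparison asks which genes differ between crypts with and without Setdb1, in a study concerned with genome stability, death of stem cells by necroptosis and inflammation of the bowel. Crypts of all 5 knockout libraries had more RNA of a fetal and regenerative epithelial type and of some heat shock genes, and less of gasdermin C genes and of lactase. Targets of p53 were high in VEMD2, VEMD3 and VEMD4 and near the WT level in VEMD6 and VEMD8. Interferon-stimulated genes were highest in VEMD4. Markers of Paneth and enteroendocrine cells were far lower in VEMD6 and VEMD8, while enterocyte markers were lower in VEMD2 and VEMD3 and higher in VEMD6. Percentiles given with some medians of gene lists are their place among 10000 random lists matched on expression, as a description of these libraries.

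**Figure D1:**
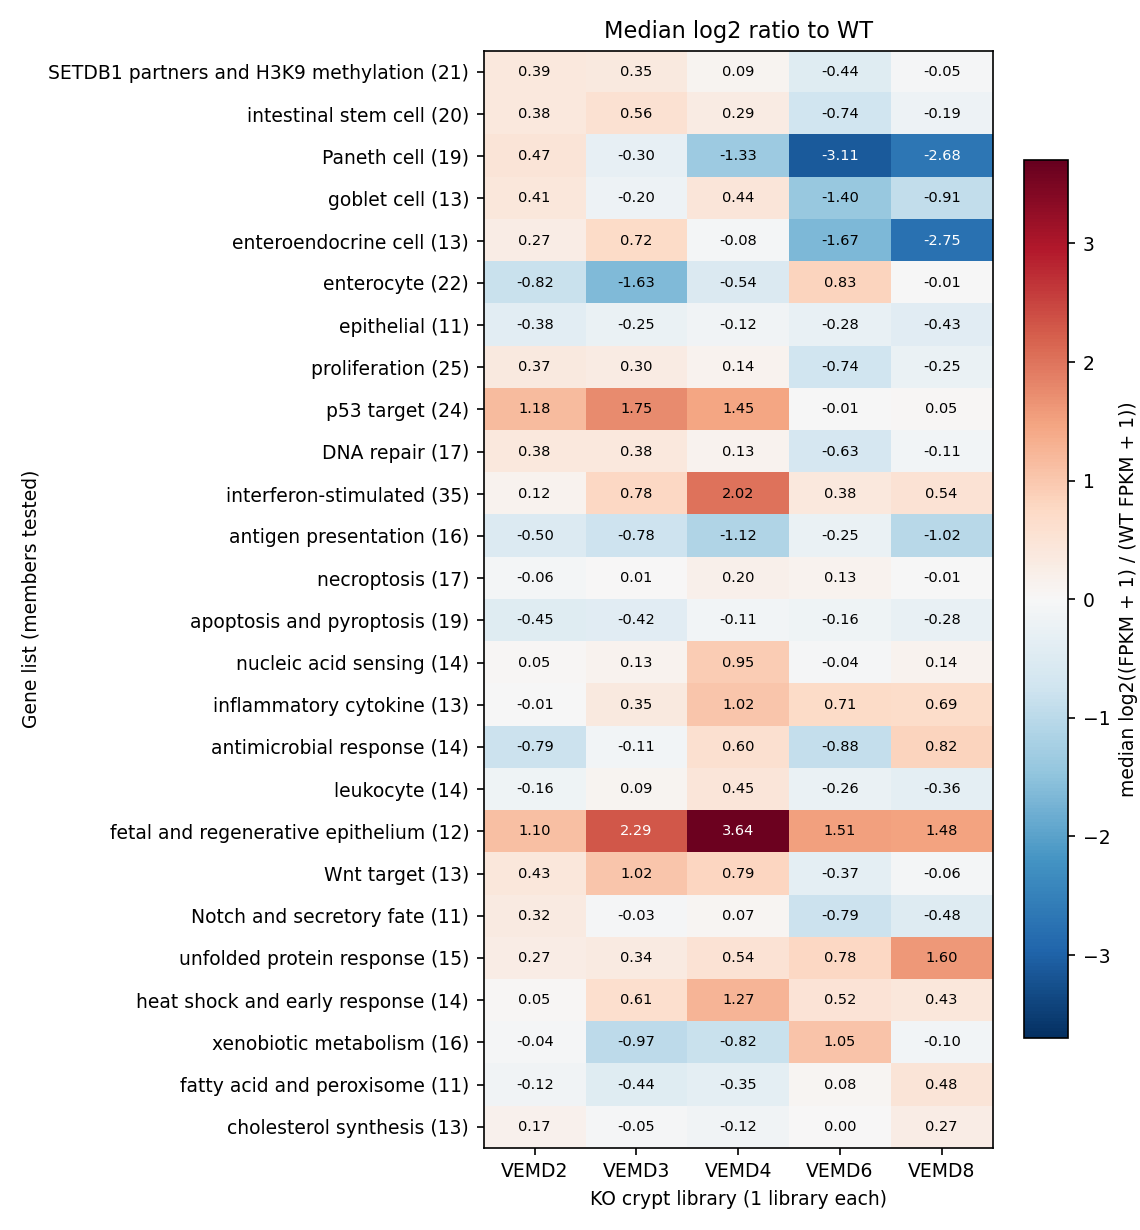
Median log2 ratio to the WT crypt library of each gene list (rows, with the number of members tested) in each knockout library (columns), as color and as a number. The fetal and regenerative list is highest in VEMD4, at 3.64, and the Paneth cell list lowest in VEMD6, at -3.11.

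Of 10862 genes tested, 62 were at least 2-fold higher than WT in all 5 knockout libraries and 68 were at least 2-fold lower. Among the highest was Ly6d, a surface protein of the Ly6 family, at 1.72 FPKM in WT and between 23.9 in VEMD3 and 138 in VEMD4. Ly6a, known as Sca-1 and a mark of regenerating epithelium, was at 37.3 in WT, 367.5 in VEMD2, 1075 in VEMD4 and 275 in VEMD8. Clu, the secreted chaperone of revival stem cells, was at 0.38 in WT and 77.2 in VEMD4. Mboat1, a lysophospholipid acyltransferase, had log2 ratios from 3.00 to 3.91. Ddah1, which breaks down methylated arginines, had ratios from 2.88 to 4.30, and Cd84, a receptor of the SLAM family, from 2.54 to 5.91. Khdc1a, of a family active in oocytes and early embryos, was at 0.16 in WT and 69.6 in VEMD4. Eno1b, an intronless near copy of the enolase gene Eno1, was at 0.62 in WT and between 96.7 and 245 in the knockouts. That value is uncertain because reads of Eno1 and its copy are hard to tell apart. The chaperones Hspa1a and Hspa1b, near copies of each other and uncertain for the same reason, had log2 ratios from 2.07 to 3.73 and from 2.39 to 3.77.

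Among the genes lower in all 5 libraries were Gsdmc2, Gsdmc3 and Gsdmc4, pore-forming gasdermins that lie side by side on chromosome 15 and resemble each other, so that their single values are uncertain. Gsdmc4 was at 82.5 FPKM in WT, 5.19 in VEMD2 and 0.23 in VEMD3, and was listed at 0 in VEMD8. Gsdmc2 was at 51.8 in WT and 2.32 in VEMD2, and was listed at 0 in VEMD3 and VEMD6. Selenop, the selenium carrier, was at 646 in WT and between 21.1 in VEMD8 and 138 in VEMD2. Pmp22, a membrane protein best known from myelin, was at 116 in WT and 1.42 in VEMD8. Car4, a membrane carbonic anhydrase, was at 150.5 in WT and 2.84 in VEMD8, and Cyp3a25, a drug-metabolizing oxidase, had log2 ratios from -1.85 to -4.44. Tcea3, a transcription elongation factor, Pdcd4, an inhibitor of translation, Tmem86a, a hydrolase of lysoplasmalogens, and C1qtnf12, a secreted protein of the C1q and TNF related family, had ratios of -1.66 or lower in every knockout library.

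All 5 ratios share the 1 WT library. With each knockout library as the reference in turn, 2 to 79 genes passed the same rule, against 130 with WT, and simulated libraries without any difference gave on average 24.7 to 56.7 higher genes and 25.1 to 32.0 lower genes, with up to 74 and 51 in a single simulation. The 62 higher genes exceeded every simulation with noise of VEMD2 and VEMD3, at most 37. They did not exceed those with noise of VEMD6 and VEMD8, at most 74. The 68 lower genes exceeded all simulations of both kinds. Each noise pair is 2 different knockout libraries, so real differences between them may add to this noise. Without VEMD2 the counts were 135 higher and 133 lower, and without VEMD6 they were 96 higher and 96 lower. Without both VEMD6 and VEMD8, an alternative chosen after seeing the data, they were 220 higher and 143 lower. Without VEMD2, VEMD3 and VEMD4, also chosen after seeing the data, they were 297 higher and 379 lower. With all 5 libraries and a pseudocount of 0.1 they were 143 higher and 94 lower.

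Library by library, the counts of genes at least 2-fold higher and lower than WT were 265 and 260 in VEMD2, 652 and 502 in VEMD3, 771 and 547 in VEMD4, 547 and 885 in VEMD6, and 474 and 566 in VEMD8. Rescaling to the median gene tipped the balance to 201 and 311 in VEMD2, to 498 and 635 in VEMD3, to 863 and 480 in VEMD6 and to 551 and 497 in VEMD8. A pseudocount of 5 lowered the counts in every library and tipped the balance to 85 and 140 in VEMD2 and to 258 and 319 in VEMD3. In all, 2656 genes passed the rule in at least 1 library, and 123 were higher in one and lower in another.

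Targets of p53, the transcription factor that answers DNA damage, were higher than WT in VEMD2, VEMD3 and VEMD4. Of 24 tested members, 15 were at least 2-fold higher in VEMD2, 17 in VEMD3 and 15 in VEMD4, with medians of 1.18, 1.75 and 1.45, each at a percentile of 100. In VEMD6 and VEMD8 only 2 and 1 members were 2-fold higher, with medians of -0.01, or 0.13 after rescaling, and 0.05. Phlda3, an inhibitor of Akt signaling, was at 0.27 FPKM in WT, 21.6 in VEMD2, 48.2 in VEMD3 and 33.8 in VEMD4, and at 0.36 and 0.12 in VEMD6 and VEMD8. Plk2, a kinase of the cell cycle, was at 0.53 in WT, 25.1 in VEMD3 and 0.63 in VEMD8. Ccng1, a cyclin, was at 22.0 in WT, 174 in VEMD3 and 22.7 in VEMD6. Cdkn1a, which encodes the inhibitor p21, differed from these in VEMD6, where its log2 ratio was 1.44. The DNA repair list of 17 genes had medians of 0.38, 0.38, 0.13, -0.63 and -0.11 from VEMD2 to VEMD8. No member was 2-fold from WT in VEMD2, VEMD3, VEMD4 or VEMD8. The histone variant H2ax had a log2 ratio of -1.25 in VEMD6, or -0.99 after rescaling.

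Interferon-stimulated genes had medians of 0.12 in VEMD2, 0.78 in VEMD3, 2.02 in VEMD4, 0.38 in VEMD6 and 0.54 in VEMD8, at a percentile of 72.3 in VEMD2 and 100 in the others. Of 35 members, 27 were at least 2-fold higher in VEMD4, against 4, 15, 6 and 8 in the other libraries in order. Oas2, a sensor of double-stranded RNA, was at 1.35 FPKM in WT, 4.79 in VEMD2, 13.8 in VEMD3, 43.8 in VEMD4 and 2.06 in VEMD6. Mx1, a blocker of viral replication, was at 1.58 in WT, 36.4 in VEMD4 and 2.15 in VEMD8. Ifit3 was at 3.19 in WT and 42.3 in VEMD4, and Rsad2, the antiviral viperin, at 6.54 and 75.5. In VEMD8, 6 members were 2-fold lower, such as the guanylate binding protein Gbp2 at -2.95 and the GTPase Iigp1 at -2.81. Leukocyte markers measured beside them had a median of 0.45 in VEMD4 over 14 genes, with Laptm5 alone 2-fold higher, and of -0.16, 0.09, -0.26 and -0.36 in VEMD2, VEMD3, VEMD6 and VEMD8, where that of VEMD3 was -0.01 after rescaling.

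Sensors of nucleic acids had a median of 0.95 over 14 genes in VEMD4, with 7 members 2-fold higher, or 5 after rescaling, among them the receptor gene Ddx58, the kinase gene Eif2ak2 and the RNA editor Adar. In the other libraries the median lay between -0.04 and 0.14, and rescaling turned its sign in VEMD2, VEMD3 and VEMD6. Sting1, the adaptor that relays signals of cytosolic DNA, was at 2.99 FPKM in WT and at 9.18, 11.6, 14.0, 3.62 and 8.55 from VEMD2 to VEMD8. Antigen presentation genes were lower in VEMD4 and VEMD8, with medians of -1.12 and -1.02 over 16 genes and 9 and 8 members 2-fold lower. In VEMD2 and VEMD3 the medians were -0.50 and -0.78, and in VEMD6 -0.25, or 0.02 after rescaling. In VEMD4, the class II genes H2-Aa and H2-Ab1 and their activator Ciita had log2 ratios of -1.78, -1.69 and -1.83.

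Necroptosis is a form of programmed death run by the kinase Ripk3 and the pore-forming Mlkl, and the series names it. The list of 17 genes had medians of -0.06, 0.01, 0.20, 0.13 and -0.01 from VEMD2 to VEMD8, at percentiles from 11.7 to 96.3, and rescaling turned the sign in VEMD3 and VEMD8. Its 2-fold higher members were Tnf, the inflammatory cytokine, in VEMD2, VEMD3, VEMD4 and VEMD8, and Zbp1, the sensor of Z-form nucleic acids, in VEMD4. Tnf was at 1.19 FPKM in WT and 5.5 in VEMD4, and its log2 ratio in VEMD2 was 1.06, or 0.99 after rescaling. Zbp1 was at 64.9 in WT and 132.5 in VEMD4, a log2 ratio of 1.02, or 0.99 after rescaling. Mlkl had a ratio of 0.98 in VEMD4. The apoptosis and pyroptosis list of 19 genes had medians of -0.45, -0.42, -0.11, -0.16 and -0.28, where that of VEMD6 was 0.05 after rescaling. Its 4 members lower in all 5 libraries were the gasdermins Gsdmc2, Gsdmc3 and Gsdmc4 and the inflammasome adaptor Pycard, at 185 in WT and 28.7 in VEMD4.

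The fetal and regenerative epithelium list had the highest median of all lists in VEMD3, VEMD4 and VEMD6. Its medians over 12 genes were 1.10, 2.29, 3.64, 1.51 and 1.48 from VEMD2 to VEMD8, at a percentile of 100 in each, and 7, 11, 12, 6 and 8 members were 2-fold higher. Their size depends on the pseudocount: the medians of VEMD2 and VEMD3 were 0.46 and 1.31 with 5 FPKM and 1.95 and 3.53 with 0.1, and that of VEMD4 was 2.42 with 5. The 5 members higher in all 5 libraries were Ly6a, Ly6d, Clu and the growth factors Areg and Ereg. Areg was at 12.5 FPKM in WT and 121 in VEMD6. Anxa1, a phospholipid-binding protein, was listed at 0 in WT and at 19.2 in VEMD4. Members under 1 FPKM in WT, such as Anxa1 and Clu, passed the filter through the knockouts. Without the filter, no median of this list left its bootstrap interval. Inflammatory cytokine genes had medians of -0.01, 0.35, 1.02, 0.71 and 0.69 over 13 genes, and 7 were 2-fold higher and 2 lower in VEMD4. The alarmin Il33, which both lists hold, was at 4.89 in WT, 27.5 in VEMD3 and 96.7 in VEMD4. Ccl20, which attracts lymphocytes, was at 4.57 in WT, 0.43 in VEMD2 and 35.7 in VEMD8.

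**Figure D2:**
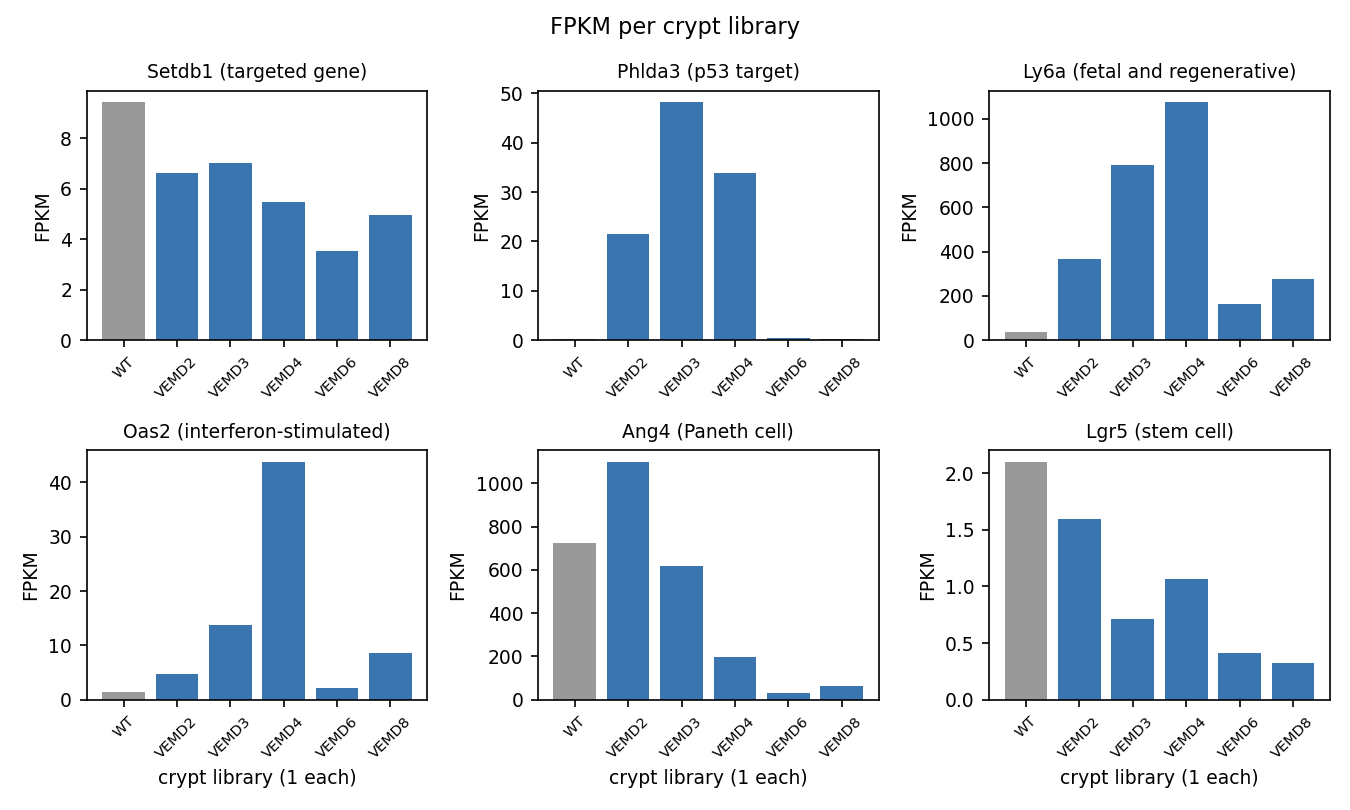
FPKM (linear axis from 0) in each of the 6 crypt libraries, 1 bar per library with WT in gray, for Setdb1 and 1 gene each of the p53, regenerative, interferon, Paneth cell and stem cell lists. Phlda3 is at 48.2 in VEMD3 and 0.12 in VEMD8, while Ang4 is at 1099 in VEMD2 and 31.3 in VEMD6.

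Genes of the absorptive and secretory cells differed between libraries in direction. Enterocyte markers had medians of -0.82, -1.63, -0.54, 0.83 and -0.01 over 22 genes from VEMD2 to VEMD8, where that of VEMD8 was 0.06 after rescaling. There were 10, 19 and 7 members 2-fold lower in VEMD2, VEMD3 and VEMD4, and 8 higher in VEMD6, at a percentile of 100, or 13 after rescaling. Alpi, the brush border alkaline phosphatase, was at 214 FPKM in WT, 62.0 in VEMD2, 43.7 in VEMD3, 1585 in VEMD6 and 925 in VEMD8. Lct, lactase, was lower in all 5 libraries, from 65.1 in WT to 0.39 in VEMD8. Paneth cell markers had medians of 0.47, -0.30, -1.33, -3.11 and -2.68 over 19 genes, with 11, 15 and 14 members 2-fold lower and a percentile of 0 in VEMD4, VEMD6 and VEMD8. The ribonuclease Ang4 was at 724 in WT, 1099 in VEMD2, 196 in VEMD4, 31.3 in VEMD6 and 63.0 in VEMD8. Of the defensins, which are near copies with uncertain single values, Defa5 and Defa26 had ratios of -4.57 and -4.30 in VEMD6, while Defa3 and Defa21 were listed at 0 in WT and at 26.1 and 11.8 there.

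Enteroendocrine markers had medians of 0.27, 0.72, -0.08, -1.67 and -2.75 over 13 genes, and 11 and 12 members were 2-fold lower in VEMD6 and VEMD8. The median of VEMD8 was -1.54 with a pseudocount of 5 FPKM and -3.42 with 0.1. Gcg, the proglucagon gene, was at 35.9 FPKM in WT, 83.6 in VEMD3 and 0.67 in VEMD8, and the incretin gene Gip at 121 in WT and 5.84 in VEMD8. Goblet cell markers had medians of 0.41, -0.20, 0.44, -1.40 and -0.91 over 13 genes, with 10 and 6 members lower in VEMD6 and VEMD8. Zg16, a lectin of the mucus layer, was at 1659 in WT, 83.7 in VEMD6 and 107 in VEMD8. The 4 tuft cell genes tested had medians of 0.34, 0.05, 0.22, -0.44 and 0.09. Rescaling turned the sign in VEMD3, and without the filter on expression the medians of VEMD3, VEMD4 and VEMD8 were -0.22, -0.37 and -0.53, so the direction of this list is uncertain there. Broad epithelial markers had medians from -0.43 to -0.12 over 11 genes.

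Stem cell markers stood apart between libraries as well, with medians over 20 genes of 0.38, 0.56, 0.29, -0.74 and -0.19 from VEMD2 to VEMD8. In VEMD3, 8 members were 2-fold higher and in VEMD6, 9 were 2-fold lower, against 4 and 4 after rescaling. Lgr5, Olfm4, Smoc2 and Aqp1 were lower than WT in all 5 libraries, and so departed from the medians in VEMD2, VEMD3 and VEMD4. Lgr5, the receptor that marks cycling stem cells, was at 2.1 FPKM in WT and at 1.6, 0.71, 1.07, 0.41 and 0.32 in the knockouts, and Olfm4 at 574 in WT, 276 in VEMD3 and 129 in VEMD4. Ascl2, a transcription factor of stem cells that went with the medians, was at 3.55 in WT, 9.99 in VEMD3 and 1.65 in VEMD6. The 4 reserve stem cell genes had medians of 0.59, 0.93, 0.47, -0.50 and -0.12. Wnt targets had medians of 0.43, 1.02, 0.79, -0.37 and -0.06 over 13 genes. Among them Cd44 was at 11.4 in WT and 56.1 in VEMD3, while Myc and Ccnd1, which drive growth, had ratios of -1.66 and -1.75 in VEMD6. Proliferation genes had medians of 0.37, 0.30, 0.14, -0.74 and -0.25 over 25 genes. In VEMD6, 7 members were 2-fold lower, such as Birc5 and Cdk1, but none after rescaling, when the median was -0.48.

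Antimicrobial genes had medians of -0.79, -0.11, 0.60, -0.88 and 0.82 over 14 genes. The lectin Reg3b was at 1687 FPKM in WT, 525 in VEMD2, 434 in VEMD3, 389 in VEMD6 and 9734 in VEMD8, and Retnlb, a goblet cell protein that kills bacteria, at 0.41 in WT, 28.8 in VEMD4 and 52.8 in VEMD8. The list's 1 member lower in all 5 libraries was Reg3a, at 33.9 in WT and 2.74 in VEMD6. Unfolded protein response genes had medians of 0.27, 0.34, 0.54, 0.78 and 1.60 over 15 genes, with 7 members 2-fold higher in VEMD6 and 10 in VEMD8. Hspa5, the main chaperone of the endoplasmic reticulum, was at 416 in WT and 2277 in VEMD8, and Chac1, which degrades glutathione, at 1.53 and 33.4. Heat shock and early response genes had medians of 0.05, 0.61, 1.27, 0.52 and 0.43 over 14 genes, where that of VEMD2 was -0.04 after rescaling. Their 4 members higher in all 5 libraries were Hspa1a, Hspa1b, the chaperone Hsph1, at 21.5 in WT and 179 in VEMD3, and the transcription factor Egr1, at 4.84 in WT and 26.9 in VEMD4. Xenobiotic metabolism genes had medians of -0.04, -0.97, -0.82, 1.05 and -0.10 over 16 genes. Gsta1 and Gsta3, glutathione transferases with close relatives and so uncertain, were higher in all 5 libraries, and Cyp1a1, a target of the aryl hydrocarbon receptor, was at 0.93 in WT and 95.5 in VEMD6.

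Loss of this methyltransferase is known from other cells to release germline genes. Only 4 of 30 germline genes, 25 of them with values, were high enough to test, with medians of 0.30, 0.78, 1.01, 0.09 and 0.71. Tdrd1, Tdrd12 and Tex19.1, under 1 FPKM in WT, passed the filter only through the knockouts. The positive medians thus follow in part from the filter, and each interval over members reached below 0. Tex19.1, normally silenced outside germ cells, was listed at 0 in WT and at 0.20, 4.54, 16.0, 13.1 and 19.9 from VEMD2 to VEMD8. Of the clustered protocadherins only Pcdhgc3 could be tested, with log2 ratios of 1.04, 1.31, 0.97, 0.26 and 0.42 from VEMD2 to VEMD8. Pcdhgc3 was at 0.7 FPKM in WT, so it too passed the filter through the knockouts. Of other cells that a crypt preparation could hold, 14 of 22 leukocyte genes could be tested, 2 of 15 stromal and endothelial genes, 2 of 11 genes of gut nerve and muscle, 1 of 11 pancreas genes and none of 5 red blood cell genes. The table holds no values for the listed genes of X inactivation and of the mitochondrial genome. The 4 genes of the Y chromosome were all within 2-fold of WT, with medians from -0.37 to 0.08.

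The second comparison sets VEMD8 against VEMD2 and so does not use the WT library. In VEMD8, Paneth and enteroendocrine genes and p53 targets were lower and unfolded protein response, antimicrobial and enterocyte genes higher than in VEMD2. Whether the crypts of both libraries came from the same stretch of gut is open, as set out further below. There were 414 genes at least 2-fold higher and 461 lower, and 545 and 350 after rescaling. The Paneth cell median was -2.84, with 15 of 19 members 2-fold lower, and the enteroendocrine median -2.73, with 12 of 13 lower. The p53 median was -1.24, with 13 of 24 members lower, among them Phlda3 at -4.33 and Trp53inp1 at -2.92. The unfolded protein response median was 1.33, with 11 of 15 higher, among them Chac1 at 3.52 and Trib3, a pseudokinase induced by stress, at 2.12. The antimicrobial median was 1.30, with 7 of 14 members higher and 2 lower, Reg3b at 4.21 and Reg1 at 4.05. The enterocyte median was 0.80, with 8 of 22 higher, 1 lower and 13 within 2-fold, Alpi at 3.88 and Lct at -4.17. Other list medians were -1.40 for goblet cell, -0.74 for stem cell, -0.54 for reserve stem cell, -0.84 for Wnt target, -0.66 for proliferation, -0.55 for DNA repair, -0.61 for antigen presentation, 0.74 for inflammatory cytokine, 0.24 for heat shock, 0.15 for germline, 0.12 for nucleic acid sensing, 0.11 for necroptosis, -0.31 for leukocyte, -0.23 for tuft cell, -0.22 for xenobiotic and 0.01 for fetal and regenerative genes. The interferon-stimulated median was 0.36, with an interval over members from -0.47 to 0.69, while 5 members were 2-fold higher and 9 lower, or 8 and 7 after rescaling. For apoptosis and pyroptosis the median was -0.09, or 0.08 after rescaling, for epithelial genes -0.07, or 0.10, and for the Y chromosome -0.05, or 0.11.

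Among the genes highest in VEMD8 against VEMD2 were Sult6b2, a sulfotransferase, at 1.13 FPKM in VEMD2 and 393 in VEMD8, and Akp3, an intestinal alkaline phosphatase, at 0.54 and 173. Gulo, the enzyme of vitamin C synthesis, was at 3.03 and 206, and Anxa10, an annexin of the stomach, at 0.07 and 39.6. Gml2, a relative of the Ly6 proteins, was at 0.45 and 44.1, and Retnlb and Ccl20 were at log2 ratios of 5.62 and 4.68. Cfhr2, related to complement factor H, was listed at 0 in VEMD2 and at 33.2 in VEMD8. The near copies Rpl34-ps1 and Hmga1b were at 1.17 and 0.05 in VEMD2 and at 279 and 68.6 in VEMD8, values that are uncertain because of their parent genes. Among the lowest were Gcg, at 68.1 and 0.67, and Fabp6, the bile acid carrier of the ileum, at 51.7 in VEMD2, 0.38 in VEMD8 and 2.27 in WT. The chemokine Ccl6 was at 167 and 4.73, the GTPase Tgtp1 at 67.5 and 1.34, the peptidase Naaladl1 at 109 and 2.87, and Enpp7, the intestinal sphingomyelinase, at 42.8 and 0.89. The defensins Defa22, Defa39 and Defa40 had log2 ratios of -4.79, -4.50 and -4.62, and Defa32 was listed at 0 in VEMD8.

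The third comparison concerns transposable elements, which histone methylation by Setdb1 is known to silence. Endogenous retroviruses of the ERVK class were mostly higher in the mutant column of the authors' deposited table of repeats, above all the internal parts IAP-d-int and MMERVK10D3_I-int, and the listed LINE-1 element was lower. The table names no tissue, and among the sample titles only the stem cell pair carries a MUT label. It lists 71 features, 44 higher and 27 lower by the authors' deposited log2 fold change, and the highest adjusted p in the authors' deposited table is 0.0465, by a test that is not stated. Features with a higher p are thus not listed, and the counts are shares of a selected set. If each column is 1 library, as in every group of samples here, this p does not measure variation between mice. Of 47 features with long terminal repeats (LTR), 29 were higher and 18 lower, and 18 and 11 were so at least 2-fold. The 24 features outside LTR were higher in a like share, with 15 higher and 9 lower, among the higher ones both ribosomal RNA features and 3 of 4 tRNA features. Of 20 ERVK features 15 were higher, 10 of them at least 2-fold, and 1 of the 5 lower was 2-fold lower. The 14 ERV1 features were split 9 to 5, the 4 ERVL features 2 to 2 and the 3 Gypsy features 1 to 2, and both features of the ERVL-MaLR type were lower. Internal parts of LTR elements, which hold the viral genes, were higher in 14 of 18 cases, while other LTR features were split 15 to 14.

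**Figure D3:**
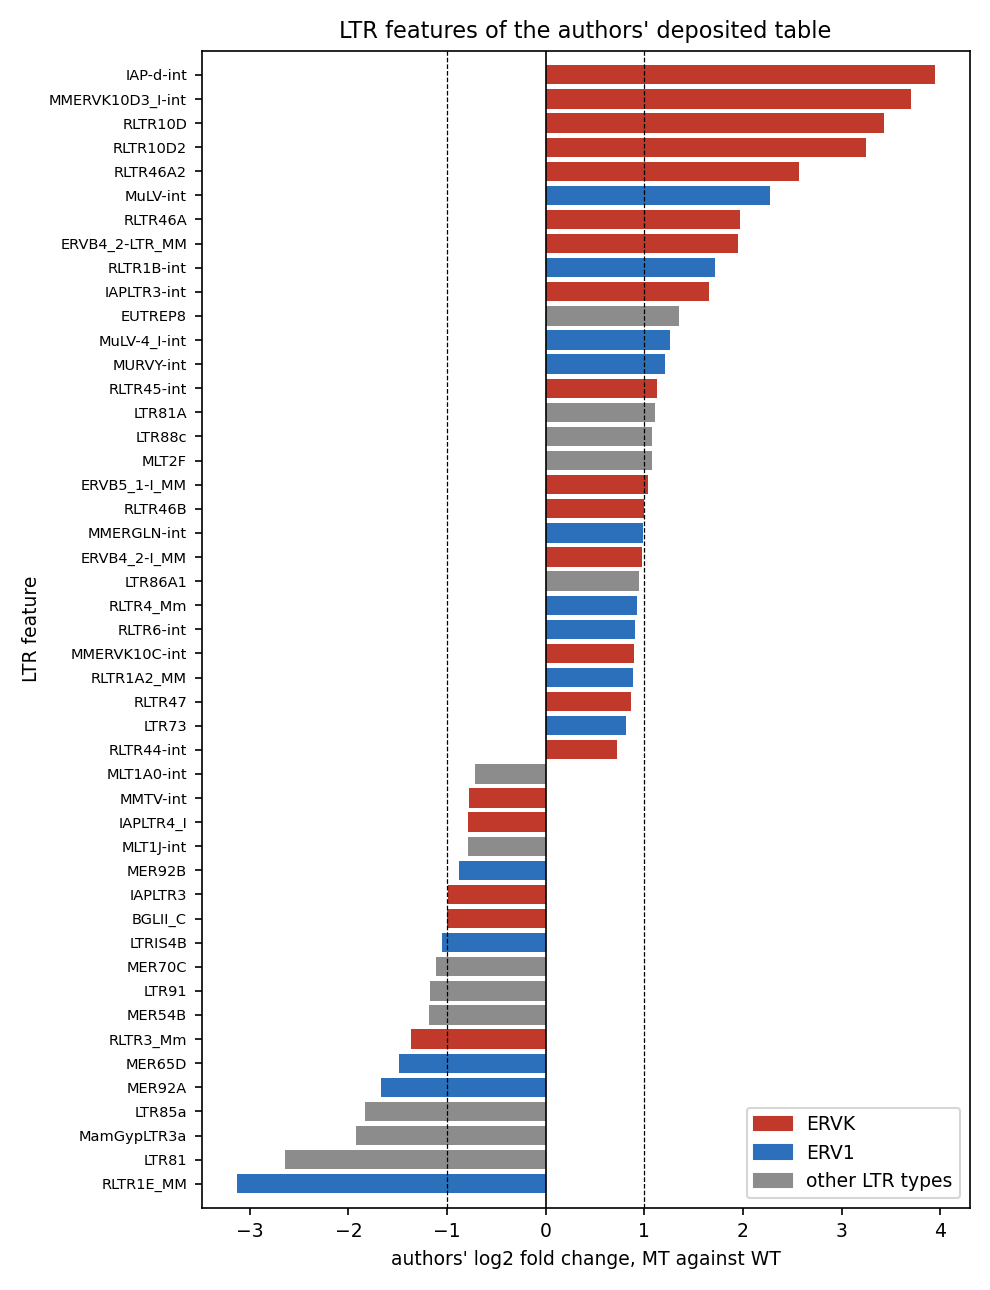
The authors' log2 fold change of mutant against WT for each of the 47 listed LTR features, 1 bar per feature, colored by type, with dashed lines at 2-fold. ERVK features reach 3.95 and ERV1 features span 2.28 to -3.13.

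The feature highest among LTR elements in the authors' deposited table was IAP-d-int, an internal part of an intracisternal A particle, with a log2 fold change of 3.95. MMERVK10D3_I-int followed at 3.71, RLTR10D at 3.43, RLTR10D2 at 3.25 and RLTR46A2 at 2.57 in the same deposited table. MuLV-int, of the murine leukemia viruses, was at 2.28, RLTR46A at 1.98 and ERVB4_2-LTR_MM at 1.95. The lowest were RLTR1E_MM at -3.13, LTR81 at -2.64, MamGypLTR3a at -1.92 and LTR85a at -1.83. By the fixed name groups, IAP had 2 features higher and 2 lower, MMERVK10C 2 higher, other ERVK names 8 higher and 1 lower, ERV1 names 6 higher and 3 lower, and MaLR names 1 higher and 2 lower. These groups go by name alone and cross the authors' types. The higher MaLR name is typed ERVL, and a lower ERV1 name is typed ERVK. In the IAP group IAPLTR3-int was at 1.66, IAPLTR3 at -0.98 and IAPLTR4_I at -0.79. The 1 LINE-1 feature, L1MdMus_I, was at -1.95. No ETn or MusD, MERVL or MT2, or SINE feature was listed. The threshold of 1.5-fold gave 29 higher and 18 lower LTR features.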

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

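The test of gut region below was prompted by values already seen, but its rule was fixed before its markers were examined. The tests of scale, of cell mixture, of a few abundant genes and of near copies were chosen only after the results were seen. The following list medians, of lists with at least 8 tested genes, stood out because knockout libraries lay on opposite sides of WT by at least 0.5 on each side, and none of these differences was tested, since each rests on 1 library. The stem cell median differed by 1.3 between VEMD3 and VEMD6, the enteroendocrine median by 3.47 between VEMD3 and VEMD8, and the enterocyte median by 2.46 between VEMD6 and VEMD3. The antimicrobial median differed by 1.7 between VEMD8 and VEMD6 and the xenobiotic median by 2.02 between VEMD6 and VEMD3. Besides endogenous retroviruses, the authors' deposited repeat table lists ribosomal RNA outside the main measurement, with LSU-rRNA_Hsa higher by a log2 fold change of 3.32 and SSU-rRNA_Hsa by 3.25. How far ribosomal RNA was removed from either column's RNA is not known, and its bearing on the retroviruses was not tested.

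VEMD6 and VEMD8 stood apart from the other 4 crypt libraries in genes that mark a place along the gut. The duodenal factor Pdx1 was at 17.9 and 16.7 FPKM in them and at 0.32 or less elsewhere, Akp3 and the iron exporter Slc40a1 were over 10 in both and under 2 elsewhere, and Gcg and the peptide gene Nts were under 2 in both and over 10 elsewhere. The ileal gene Fabp6 was at 0 and 0.38 in them. It was at 2.27 in WT, 51.7 in VEMD2, 8.19 in VEMD3 and 5.54 in VEMD4, so the other 4 libraries were not alike in this gene. A plain difference in scale is argued against by the 43.9% of genes on the smaller side among those 2-fold from WT in both libraries. Crypts from a more proximal stretch of intestine may have entered these libraries: other proximal minus distal markers differed by 1.07 in VEMD6 and 0.99 in VEMD8, with intervals from -0.32 to 4.79 and from -1.07 to 5.04, but also by 1.16 in VEMD3. Of the 6 proximal markers, 3 were 2-fold higher and 0 lower in VEMD6, among them S100g at 3.67. In VEMD8, 0 were 2-fold higher and 2 lower, Ghrl at -1.98 and S100g at -1.19. The other proximal markers lay between 0.305 and 0.962 there, and the median of the 6 was 0.47, so these markers did not decide the question. Of the 5 distal markers, 1 was 2-fold lower in VEMD6 and 2 in VEMD8, among them Osr2 at -3.21 and -4.58, and 0 were 2-fold higher in either. Gcg was lower together with other enteroendocrine genes, among them Gip at -4.15 in VEMD8. With 6 and 5 markers and 1 library each, region and an effect of the knockout cannot be told apart, and a biological difference stays open and untested.

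In VEMD6, Paneth cell markers were lower and enterocyte markers higher. More villus enterocytes in place of crypt cells would lower all crypt markers alike, but the Paneth median lay below the proliferation median by -2.37, with an interval from -2.87 to -1.66, and by -2.26 without the defensins, so this mixture is argued against as the whole cause. A few genes taking up the FPKM would lower all others by 1 factor, and is argued against as well, since the Paneth median lay below that of all other tested genes by -2.87, with an interval from -3.33 to -2.16. A smaller number of Paneth cells after loss of Setdb1 could remain and was not tested. Another gut region stays open too, since the difference of 1.07 in VEMD6 given above did not decide it.

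The near copy Eno1b was at a far other level than in WT in all 5 knockout libraries, and Hmga1b and Rpl34-ps1 were so mainly in VEMD6 and VEMD8. If reads of the parent gene were split at 1 fixed share, the copy would hold the same part everywhere, but Eno1b held 0.174% of copy plus parent in WT and 41.9% in VEMD4, Hmga1b 0% and 44.7% in VEMD6, and Rpl34-ps1 0% and 49.5% in VEMD8. The parent Eno1 was at 356 FPKM in WT, lower in VEMD2, VEMD3 and VEMD4, and higher in VEMD6 and VEMD8, at 506 and 413. Hmga1 was at 231 in WT and at 79.8 and 111 in VEMD6 and VEMD8, and Rpl34 at 694, 212 and 285. A genetic variant that moves reads from parent to copy could still be the source: among the 9 values in which the copy held at least 10%, the sum of copy and parent was over 1.5-fold from WT in 5, in 3 of 5 for Eno1b, 1 of 2 for Hmga1b and 1 of 2 for Rpl34-ps1, so it cannot be told apart from a copy that is itself expressed. FPKM are scaled for gene length, so the sum of copy and parent need not stay constant when reads move between genes of unlike length. Sequence reads, which could settle the source, were not used here.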

How the results depend on the processing

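Leaving out groups of libraries was chosen after the results were seen, and all other settings were fixed in advance. The cause was not tested for any value that moved, except where fewer genes or libraries or another threshold enter by construction. No list median of at least 0.5 in size and no named gene that was 2-fold apart had another sign under an alternative. Of all values, 59 counts and Setdb1 levels, 853 list medians and 4203 values of named genes stayed within their bounds, against 36, 35 and 369 that moved. Of 888 list medians under an alternative, 22 had another sign, 5 of them with a size of at least 0.1 at first: tuft cell in VEMD4 without a filter (-0.37), antimicrobial in VEMD3 without a filter (0.05), and after rescaling antigen presentation (0.02) and apoptosis (0.05) in VEMD6 and nucleic acid sensing (-0.01) in VEMD3. For genes 2-fold from WT in all 5 libraries, a pseudocount of 0.1 gave 143 higher, a pseudocount of 5 gave 24 higher and 34 lower, a mean of at least 5 FPKM gave 41 lower, the 1.5-fold threshold 192 and 235, and the 4-fold threshold 10 and 8. Leaving out 1 library gave 63 to 135 higher and 70 to 133 lower, leaving out VEMD6 and VEMD8 220 and 143, and leaving out VEMD2, VEMD3 and VEMD4 297 and 379. Rescaling kept 47 of the 62 higher and 59 of the 68 lower genes. Per library, a pseudocount of 0.1 gave 502 higher in VEMD2, 1365 lower in VEMD6 and 738 lower in VEMD8 against VEMD2. A pseudocount of 5 gave 85 higher and 140 lower in VEMD2, 258 and 319 in VEMD3, 383 and 304 in VEMD4, 317 and 357 in VEMD6, 253 and 265 in VEMD8, and 237 and 175 in VEMD8 against VEMD2. Rescaling gave 863 and 480 in VEMD6, and a mean of at least 5 FPKM 296 lower in VEMD8 against VEMD2. The side with more genes turned with a pseudocount of 5 in VEMD2, VEMD3 and VEMD8 against VEMD2, after rescaling in VEMD2, VEMD3, VEMD6, VEMD8 and VEMD8 against VEMD2, and with a mean of at least 5 FPKM in VEMD2 and VEMD8 against VEMD2. For all 5 libraries together it turned with a pseudocount of 0.1, a mean of at least 5 FPKM and the 4-fold threshold. Setdb1 in VEMD6 was at -0.99 after rescaling.

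List medians that left their bootstrap interval with a pseudocount of 0.1 were stem cell -1.08 and DNA repair -0.84 in VEMD6, enteroendocrine -3.42 in VEMD8 and -3.73 against VEMD2, fetal 1.95 in VEMD2 and 3.53 in VEMD3, and germline 1.10 in VEMD2. With a pseudocount of 5 they were stem cell -0.40, DNA repair -0.30 and Notch -0.42 in VEMD6, enteroendocrine -1.54 and leukocyte -0.16 in VEMD8, tuft cell 0.14, DNA repair 0.22 and fetal 0.46 in VEMD2, fetal 1.31 in VEMD3, fetal 2.42 and interferon-stimulated 1.67 in VEMD4, and stem cell -0.55, Wnt -0.55 and Notch -0.35 in VEMD8 against VEMD2. After rescaling they were SETDB1 partners 0.22, leukocyte -0.01 and cholesterol -0.19 in VEMD3, proliferation -0.48, interferon-stimulated 0.64, leukocyte -0.03 and cholesterol 0.24 in VEMD6, and stem cell -0.61, epithelial 0.10, proliferation -0.49, Wnt -0.69 and Notch -0.52 in VEMD8 against VEMD2. A mean of at least 5 FPKM gave leukocyte -0.96 in VEMD8 and -0.65 against VEMD2. The 1.5-fold threshold gave 29 higher and 18 lower LTR features. Not run were all stem cell gene comparisons, their overlap with the crypts, and other pseudocounts, filters and scalings of the repeats, since only the authors' fold changes were used. The depth is unknown, so its effect on genes near 0 cannot be given.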

Other observations

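The tests of gene clusters among higher and lower genes were fixed in advance, while those limited to other name stems and that of leukocyte RNA were chosen only after the results were seen. Some groups of the crypt libraries have not been described so far. Partners of SETDB1 and other H3K9 methylation genes had medians of 0.39, 0.35, 0.09, -0.44 and -0.05 over 21 genes from VEMD2 to VEMD8, and -0.38 in VEMD8 against VEMD2. Atf7ip, which stabilizes the SETDB1 protein, was at 9.06 FPKM in WT and at 18.7, 24.9, 21.1, 13.9 and 18.3 in the knockouts, with log2 ratios over 1 in VEMD3 and VEMD4. Daxx, a histone chaperone, was at 17.1 in WT and 40.5 in VEMD4. Trim28, the corepressor that recruits SETDB1, was at 59.2 in WT and 28.6 in VEMD6, a ratio of -1.02, or -0.76 after rescaling. Notch and secretory fate genes had medians of 0.32, -0.03, 0.07, -0.79 and -0.48 over 11 genes, and -0.66 in VEMD8 against VEMD2. Atoh1, the master factor of secretory cells, was at 10.7 in WT, 3.42 in VEMD6 and 4.5 in VEMD8.

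Fatty acid and peroxisome genes had medians of -0.12, -0.44, -0.35, 0.08 and 0.48 over 11 genes, and 0.36 in VEMD8 against VEMD2. The fatty acid transporter Cd36 was the 1 member lower in all 5 libraries, at 7.09 FPKM in WT and between 0.21 and 0.57 in the knockouts, and the kinase Pdk4 was at 0.67 in WT and 11.6 in VEMD6. Cholesterol synthesis genes had medians of 0.17, -0.05, -0.12, 0.00 and 0.27 over 13 genes, and 0.04 in VEMD8 against VEMD2. Only the regulator Insig1 was 2-fold lower, in VEMD3 and VEMD4. A pair of genes without a symbol in the annotation, 13222 and 13223, were among the most abundant in WT, at 2527 and 1401, and at 0.83 and 1.32 in VEMD8. They were at 3907 and 2488 in VEMD2, 527 and 362 in VEMD3, and 40.3 and 37.9 in VEMD4. Like the Paneth gene Ang4 above, they were thus higher than WT in VEMD2 and far lower in VEMD4 and VEMD8.

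Silencing by histone methylation can cover neighboring genes, so a hypothesis is that the 62 genes higher in all 5 libraries lie in clusters. Of them, 11 (17.7%) had another such gene within 200 kb, against a mean of 3.51% and a highest value of 16.1% in 1000 random gene sets. With neighbors of another name stem the count was 9 (14.5%), against a 95th percentile of 9.68% and a highest value of 16.1% in the random sets. These 9 include Areg beside Ereg and Gm3776 beside Gsta1 and Gsta4, which are related genes under other names, so the excess may rest on gene families. The only pairs among them without such a relation were Khdc1a with Gsta3 on chromosome 1 and Rdm1 with Etv4 on chromosome 11. These pairs alone were not set against random sets. Of the 68 lower genes, 9 (13.2%) had such a neighbor, against a 95th percentile of 8.96%, but with other name stems 4 (5.88%) did, against 8.82%. Among the lower genes, clusters beyond gene families thus lay above the random mean of 3.34% but under the 95th percentile of random sets.

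More leukocytes in the VEMD4 crypts could raise interferon-stimulated genes there. The leukocyte median of 0.45 in VEMD4 was itself at a percentile of 99.1, with an interval from 0.15 to 0.56. It lay below the interferon-stimulated median by -1.57, with an interval from -1.97 to -1.18. This argues against a rise of leukocyte RNA as large as that of the interferon-stimulated genes in that library. The difference cannot exclude leukocytes rich in these RNAs, since only the medians were compared.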
